A study of Mus musculus with 3 samples.

How the data were processed

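Cytosolic RNA was measured by RNA sequencing in 3 libraries of mouse macrophages, which the labels give as biological replicates 1, 2 and 3 of 1 group. Bone marrow-derived macrophages of the C57BL/6J strain had been kept in 100 ng/ml Lipid A for 12 h, washed, left without it for 12 h, and given 100 ng/ml Lipid A again for 50 min, per the labels. The RNA was total RNA of the cytosolic fraction depleted of ribosomal RNA, from 1 µg of input, in fragments of 250 to 400 bases, per the labels. Every group, gene list, test and alternative was chosen before the data were examined, except those named as added after seeing the data. All 3 libraries carry 1 strain-level donor entry and separate samples in the labels, so the spread between them is that between cultures of 1 strain as far as the labels tell.

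For each library the authors deposited a gene table and 2 transcript tables. The expected count per gene and per transcript is an estimate of reads that need not be whole, and was deposited by the authors without normalisation. TPM, a share of transcripts after division by length, was deposited by the authors in all 3 tables and is taken over every indexed feature, short RNAs and spike-ins included. The percent of a gene's TPM on each transcript stands in a deposited column of the first transcript table; the shares printed here were computed again from TPM. A posterior SD of each expected count, deposited in the gene table, shows how far reads shared between genes leave a count open. The mm10 assembly and the GENCODE M21 annotation are named in the notes deposited with the files. Column layouts of the gene and first transcript tables are those RSEM writes, and the layout of the second transcript table is that of kallisto, but the quantifier, aligner, versions and strand setting are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense gene could not be told apart.

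The gene table holds 81881 entries: 55536 Ensembl genes, 26248 tRNA entries, 96 ERCC spike-ins and 1 phiX genome. All 55536 Ensembl identifiers matched the GENCODE M21 annotation, which gave symbols, classes and coordinates on mm10. Entries that name no gene stayed out of library sizes and tests; phiX took 0.0785%, 0.0521% and 0.0251% of expected counts in replicates 1, 2 and 3, with 95% Wilson intervals of 0.0777 to 0.0793%, 0.0515 to 0.0527% and 0.0247 to 0.0255%, the ERCC entries held 0 counts, and tRNA entries held at most 4.98 counts in a library. Of 433 listed genes, 1 (Rn7sl1) was not matched. Where a symbol had more than 1 identifier, the one with the higher mean count was used.

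Depth was 47972048, 54409437 and 53491936 expected counts over genes in replicates 1, 2 and 3. A count of 0 therefore allows up to 0.0625, 0.0551 and 0.0561 CPM (3 counts of the total), for counting error only.

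A gene was called expressed at a TPM of at least 1 in every replicate. Expected counts were rounded to whole numbers for count tests. Variation beyond counting error was tested per gene with a Poisson heterogeneity chi-square (2 degrees of freedom) against effective library sizes from TMM, for genes with a mean count of at least 10, with Benjamini-Hochberg adjustment at 0.05. The common and tagwise biological coefficients of variation came from an intercept-only edgeR fit. For 29 fixed lists (20 gene lists and 9 lists of cell type markers) the median TPM per replicate was set against 10000 random lists of the same size drawn from expressed genes, as a description only. For 17 fixed differences (4 pairs of lists, 8 marker pairs, 5 gene pairs) log2(TPM + 1) values were subtracted within each library and tested with an exact two-sided sign-flip permutation, whose smallest p with 3 replicates is 0.25. The replicate spread of each list, as its median tagwise dispersion, was compared with 10000 random lists matched on mean log2 CPM in 20 bins by a one-sided permutation test with Benjamini-Hochberg adjustment over 25 lists with at least 3 tested members. Deviations between replicates are given as log2(CPM + 0.5) with TMM library sizes, since TPM depends on the share of short RNAs. The 2 transcript tables were compared over 141767 shared transcripts.

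Genes are named by a fixed rule: the 10 highest in mean TPM; the 3 highest members of each list and, in lists with at least 8 measured members, the lowest; the genes of the fixed pairs; every nuclear-retained RNA and sex-linked gene; the 10 genes with the largest ratio of highest to lowest replicate among those with mean TPM of at least 10 past the heterogeneity test; and the 2 highest markers of each cell type. Other genes named were chosen after their values were seen, and are there as further list members.

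The steps were tested on simulated data. In Poisson counts at the real means for 13718 genes, the heterogeneity test found 33, 37, 44 and 50 of 50 genes changed 1.2, 1.5, 2 and 4-fold in 1 library, with 16 unchanged genes called. A simulated coefficient of variation of 0.2 over 13657 genes was estimated as 0.1997. Among simulated lists of 20 genes, run on 13652 genes, the spread test found 10 of 10 with the coefficient of variation raised to 0.4 and 0 of 20 left at 0.2. Simulated genes were drawn independently, so this does not cover false calls among lists of co-regulated genes. Of 200 random lists set against the level of 9548 genes, 5 lay above percentile 97.5.

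Alternatives changed the TPM minimum, the count minimum, size factors, test, threshold, pseudocount, unit, quantification, list membership, fold and share limits, and left out each replicate in turn. TPM rescaled to protein-coding genes and a fit to nuclear protein-coding genes only were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 (median-ratio size factors only) were used. No untreated, untolerised or nuclear library is part of these 3, so no fold change between conditions was computed.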

Results

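The 3 libraries held cytosolic RNA of bone marrow-derived macrophages, phagocytes grown from marrow cells of C57BL/6J mice, that had met Lipid A in 2 rounds: 12 h at 100 ng/ml, 12 h without it, then 50 min at 100 ng/ml. Lipid A is the part of bacterial lipopolysaccharide that Toll-like receptor 4 (TLR4) recognises, and a first exposure followed by rest is the usual way to make macrophages tolerant. The labels give 1 condition with 3 biological replicates, so levels within the restimulated state and their spread between replicates are what can be compared. Depth ran from 47972048 to 54409437 expected counts per library.

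Inflammatory mRNAs of quite different levels stood side by side in these cells. Without an untreated or untolerised library, the levels do not tell which mRNAs were induced, tolerant or left from the first exposure. The chemokine Ccl5 and the acute-phase gene Saa3 were among the 10 highest RNAs, and the interferon-response list and Tnf were high, whereas Il6, Il12b, Nos2 and Lif, other classic products of lipopolysaccharide-stimulated macrophages, ranged from modest to almost absent. In all, 9548 genes, 9059 of them protein-coding, reached a TPM of 1 in every replicate. Raising the minimum to a TPM of 5 left 5802 genes.

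Short non-coding RNAs headed the list by TPM. Rn7s1 and Rn7s2, the 7SL RNA genes of the signal recognition particle (chromosome 12, 69159295 to 69159594 and 69361182 to 69361481), together held 58.5% ± 4.83 of TPM and 8.81% ± 2.00 of expected counts (SD, n = 3); they are near-identical copies that share reads, so the division between them is uncertain. Rn7sk, an RNA that restrains transcription elongation, followed with a TPM of 36990 ± 12320, then Rpph1, the RNA of ribonuclease P, at 28520 ± 9385, and Rmrp at 8825 ± 2577. The highest mRNAs were those of the ferritin chains Fth1 (18760 ± 1145) and Ftl1 (8216 ± 977), the chemokine Ccl5 (4810 ± 565; chromosome 11, 83525778 to 83530518), the actin-binding peptide Tmsb4x (4551 ± 685) and the acute-phase protein Saa3 (3857 ± 1287; chromosome 7, 46711998 to 46715700). Because short RNAs took different shares, the median expressed coding gene had a TPM of 9.78, 7.29 and 10.3 in replicates 1, 2 and 3, against 31.1, 31.8 and 32.9 CPM (expected counts scaled to TMM library sizes). Directions between replicates are therefore given in CPM.

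**Figure D1:**
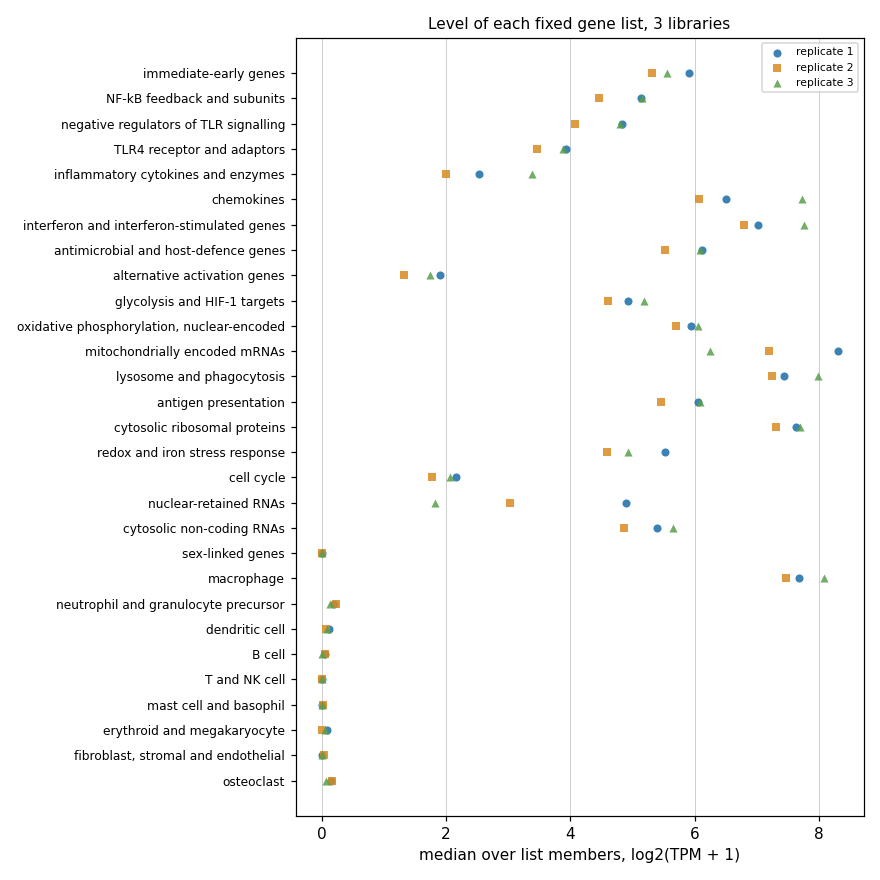
Median log2(TPM + 1) of each of the 29 fixed gene lists, with 1 point per replicate. Macrophage markers lie near the top, at a median TPM of 217, and the lists of markers of other cell types lie near 0.

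Transcripts of genes known from the immediate response to TLR4 were abundant. Without an unstimulated library, the levels do not show whether Lipid A had induced these transcripts here. The immediate-early genes, transcription factors and phosphatases switched on within minutes of stimulation, had a median TPM of 48.1 ± 10.5 (SD, n = 3), with 20 of 23 members at a TPM of 1 or more in every replicate; Egr1 stood at 256 ± 92.9, Junb at 248 ± 50.9 and Klf6 at 236 ± 85.2, while Fosl1 was lowest at 0.00667. NF-kB subunits and feedback genes of the NF-kB pathway formed 1 list, with a median of 29.9 ± 7.69 and all 17 members expressed. The list was led by the inhibitor Nfkbia (559 ± 194), the ubiquitin-editing enzyme Tnfaip3 (225 ± 97.8) and Nfkbiz (180 ± 70.8). Tnip2 was its lowest member at 6.06 ± 1.22. Among 20 negative regulators of TLR signalling, median 23.4 ± 6.59, 17 were expressed, headed by the mRNA-decay factor Zfp36 (543 ± 161), Rgs1 (456 ± 273) and the adaptor Pik3ap1 (272 ± 46.0); the decoy receptor Il1r2 was lowest at 0.323 ± 0.141. The receptor and its adaptors had a lower median, 12.7 ± 2.33, which 81.4% of random lists of expressed genes did not reach, with Cd14 at 200 ± 77.4, Ikbke at 70.2 ± 16.8 and Irf5 at 67.6 ± 17.6, and Lbp lowest at 0.710 ± 0.111. The medians of the other 3 lists lay at percentile 99.78 or above.

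Inflammatory cytokines and enzymes were split. Tnf reached a mean TPM of 1180 ± 545 (chromosome 17, 35199381 to 35202007), Il1b 217 ± 73.8 and Il1a 193 ± 79.5, but the list's median was 5.74 ± 3.30, and 5 of 18 members had a mean TPM under 1. That median lay at percentile 13.4 of random lists, which hold expressed genes alone; with members of mean TPM of at least 1 it was 9.88, at percentile 50.5, and without replicate 3 it was 3.90, at percentile 1.74. Il6 stood at 7.06 ± 4.78 (chromosome 5, 30013114 to 30019981), Nos2, the inducible nitric oxide synthase, at 5.73 ± 4.75, Il12b at 3.30 ± 0.823 and Lif, the lowest, at 0.0367 ± 0.0289. Chemokines had a median of 122 ± 77.3, or 77.9 without replicate 3, and 15 of 17 were expressed, with Cxcl10 at 801 ± 634 and Ccl3 at 625 ± 341 after Ccl5; Ccl17, an attractant made by alternatively activated cells, was at 0.0333 ± 0.0289.

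**Figure D2:**
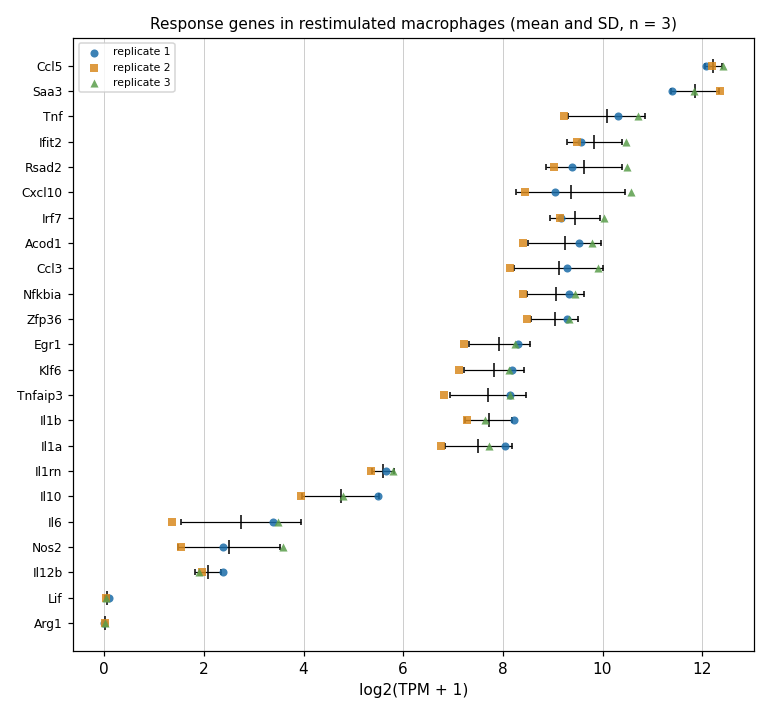
log2(TPM + 1) of 23 response genes in each of the 3 replicates, with the mean (vertical tick) and SD (bar) over replicates. Ccl5, Saa3 and Tnf lie at the top, and Il6, Nos2, Il12b, Lif and Arg1 at the bottom.

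Set against the cytokine list within each library, the 4 response lists compared with it were higher in all 3 replicates. On the log2(TPM + 1) scale the chemokine median exceeded the cytokine median by 4.13 ± 0.19 (SD, n = 3), the antimicrobial genes by 2.98 ± 0.52, the immediate-early genes by 2.96 ± 0.67 and NF-kB feedback and subunits by 2.28 ± 0.44. Within gene pairs, the anti-inflammatory cytokine Il10 (TPM 28.4 ± 14.9) exceeded Il12b by 2.66 ± 0.60 and Il6 by 2.01 ± 0.65, whereas the interleukin-1 antagonist Il1rn (47.8 ± 7.43) lay below Il1b, with a difference of -2.12 ± 0.40, and Tnfaip3 lay below Tnf, at -2.38 ± 0.20. Arg1, the arginase of alternative activation, was almost absent (0.00667 ± 0.00577) and lay below Nos2 at -2.50 ± 1.03. With 0, 1 and 1 counts Arg1 was under the 3 counts that a count of 0 allows, so the size of this difference is set by the pseudocount (-5.43 with 0.1) and gives no fold. Each of these 9 differences had 1 sign in 3 of 3 replicates and an exact sign-flip permutation p of 0.25, the smallest that 3 replicates allow.

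The interferon arm was strongly represented. All 27 interferon-stimulated genes were expressed, with a median TPM of 151 ± 56.4 (SD, n = 3), percentile 100.0 of random lists. The antiviral genes Ifit2 (959 ± 392; chromosome 19, 34550694 to 34576419) and Rsad2 (873 ± 487) and the transcription factor Irf7 (729 ± 274) led, and Ifnb1, the interferon-beta gene itself, was lowest at 4.77 ± 4.60. Antimicrobial and host-defence genes had a median of 60.0 ± 12.9, or 111 over members of mean TPM of at least 1, with 13 of 18 expressed: after Saa3 came the lysozyme Lyz2 (3417 ± 340) and Acod1, which makes itaconate (652 ± 283), and Ptx3 was lowest at 0.01. Antigen presentation genes had a median of 58.4 ± 13.5 and all 14 were expressed, with the class I components B2m (3566 ± 784), H2-K1 (2357 ± 345) and H2-D1 (1747 ± 328) far above the class II regulator Ciita (1.72 ± 0.468). Alternative activation genes were low, at a median of 2.21 ± 0.632 and percentile 0.03, with 9 of 17 expressed; over members of mean TPM of at least 1 the median was 5.42, at percentile 12.6. The interleukin-4 receptor chain Il4ra (37.4 ± 6.90), Tgm2 (34.2 ± 15.4) and the mannose receptor Mrc1 (25.6 ± 9.58) were the highest members.

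Housekeeping and phagocyte functions were high. Lysosome and phagocytosis genes, all 24 expressed, had a median TPM of 192 ± 53.7 (SD, n = 3), with the proteases Ctsd (2958 ± 618) and Ctsb (2150 ± 660) and the glycoprotein Gpnmb (1615 ± 478) at the top and the proton pump subunit Atp6v0d2 lowest (5.97 ± 1.09). Cytosolic ribosomal protein genes, all 21 expressed, had a median of 186 ± 25.3, from Rplp1 (465 ± 111), Rps9 (337) and Rpl32 (257 ± 39.3) down to Rpl5 (20.2 ± 5.83), and nuclear-encoded oxidative phosphorylation genes, all 20 expressed, one of 59.0 ± 7.19, from Atp5b (242 ± 45.2) to Ndufv1 (11.8 ± 1.66). Glycolysis and HIF-1 target genes had a median of 29.4 ± 5.98, led by Gapdh (364 ± 73.2), Aldoa (179 ± 32.4) and Pkm (179 ± 35.5), with the HIF target Egln3 at 0.0167 ± 0.0116. Redox and iron stress genes had a median of 32.4 ± 11.2; beside the ferritins, the autophagy receptor Sqstm1 stood at 460 ± 217 and Nqo1 at 0.450 ± 0.0265. Cell cycle genes were low, median 3.04 ± 0.537 and percentile 0.39, or 4.55 and 3.21 over members of mean TPM of at least 1, although the cell cycle inhibitor Cdkn1a reached 187 ± 49.6, Pcna 70.5 ± 14.4 and Ccnd1 14.5 ± 4.79; the mitotic kinase Plk1 stood at 0.270 ± 0.140. Mitochondrially encoded mRNAs had a median of 178 with a wide SD of 123, and of 111 without replicate 1, led by mt-Atp8 (1180 ± 872), mt-Co1 (897 ± 579) and mt-Nd6 (231 ± 145); mt-Co2 (3.72 ± 3.25) and mt-Co3 (35.6 ± 24.3) have large posterior SDs from shared reads and are uncertain.

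Markers identified the cells as macrophages. All 15 macrophage markers were expressed at a median TPM of 217 ± 48.0 (SD, n = 3), from Lyz2, C1qb (968 ± 161) and Mpeg1 (819 ± 169) down to Cd33 (5.89 ± 2.38). Medians of the other 8 marker lists lay between 0.00333 and 0.143. The macrophage median exceeded each in 3 of 3 replicates, by a mean over replicates of 7.55 to 7.74 on the log2(TPM + 1) scale (exact sign-flip permutation p of 0.25 for each). With the other medians near 0 the pseudocount sets this size: with 0.1 the differences were 9.79 to 11.01. Over members of mean TPM of at least 1 they were smaller, down to 3.63 for T and NK cell genes and 1.09 for erythroid and megakaryocyte genes, where Pf4 alone remained. Members of these lists with a mean TPM of at least 1 were the neutrophil genes Csf3r (33.4 ± 8.40), S100a9 (5.41 ± 1.07), S100a8 (3.80 ± 0.360) and Mmp8 (2.11 ± 0.378), the platelet chemokine Pf4 (102 ± 24.7), the T cell co-receptor Cd4 (16.6 ± 3.81), the endothelial receptor Kdr (6.11 ± 5.38), the osteoclast genes Nfatc1 (12.3 ± 1.36) and Acp5 (11.4 ± 1.22), Cd79b (1.33 ± 0.497) among B cell genes and Ccr7 (1.12 ± 0.115) among dendritic cell genes. Among the next genes of these lists, Pecam1 stood at 0.717, Ighm at 0.5, Itgax at 0.387, Ppbp at 0.167 and Lck at 0.130. The mast cell list had Kit at 0.263 and Prss34 at 0.0533 as its highest genes. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty held 0 counts in all 3 libraries, while Xist, the X-inactivation RNA, was present in each, at 28.9, 7.13 and 2.54 TPM; the cultures thus carried the RNA pattern of female cells.

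Nuclear-retained RNAs were detectable in the cytosolic fraction and differed widely between replicates. Malat1 (chromosome 19, 5795690 to 5802672) had a TPM of 647 ± 530 (SD, n = 3), which on the log2 scale is 5.84 ± 1.18 above the median expressed coding gene. It stood at 5964, 3090 and 1426 CPM in replicates 1, 2 and 3, a 4.18-fold difference between replicates 1 and 3. With 0.5 added to each CPM, Neat1, the scaffold of paraspeckles, was 4.95-fold higher in replicate 1 than in replicate 3, Gm26917 9.40-fold and Xist 11.4-fold. In TPM relative to the median expressed coding gene, Neat1 differed less. It stood there at 2.17, 2.14 and 0.88 log2 in replicates 1, 2 and 3. Kcnq1ot1 (8.68-fold) and Airn (2.21-fold) are annotated as antisense to other genes, and without a stated strand setting their values are uncertain. Gm26917 (chromosome 17, 39843013 to 39846341) lies next to the rRNA-annotated gene CT010467.1 (39846353 to 39848827). The small RNAs Rn7sk (1.76-fold), Rmrp (1.39-fold) and the low Pvt1 (1.13-fold) differed less, and Tsix and Meg3 held 0 counts. Cytosolic non-coding RNAs had a median TPM of 39.5 ± 10.7; the growth-arrest transcript Gas5 stood at 24.95, 22.2 and 21.8 CPM and 2900097C17Rik at 450, 496 and 479, but other members varied more: Snhg1 stood at 5.81, 3.20 and 3.40 CPM, Zfas1 at 31.6, 28.4 and 45.5 and Rn7s1 at 34570, 55590 and 42190. The fixed list also holds Rpph1, although ribonuclease P acts in the nucleus, and it shifted as Rn7sk did (1.71-fold). Dancr was lowest at a TPM of 0.117 ± 0.108. The spread of this list, 0.218 against 0.187 for level-matched lists, was not wider than chance (permutation, adjusted p = 0.0823), but was without replicate 3 (permutation, adjusted p = 0.0175) and at a mean count of at least 100 (permutation, adjusted p = 0.027).

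**Figure D3:**
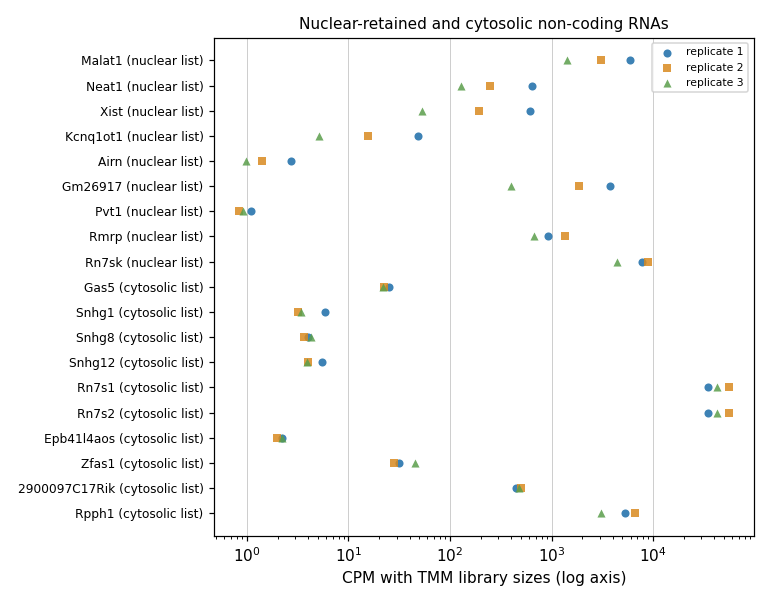
CPM with TMM library sizes (log axis) of nuclear-retained and cytosolic non-coding RNAs with more than 0.5 CPM in each replicate, 1 point per replicate. Malat1 runs from 5964 in replicate 1 to 1426 in replicate 3; of the cytosolic RNAs, Gas5 stays between 21.8 and 24.95 and Zfas1 runs from 28.4 to 45.5.

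Several lists of genes that respond to stimulation repeated less well than other genes of similar level. Inflammatory cytokines and enzymes had a median biological coefficient of variation of 0.337 against 0.161 for level-matched random lists (one-sided permutation, adjusted p = 0.0005, near the smallest it can give), chemokines 0.306 against 0.153 (permutation, adjusted p = 0.0005), interferon-stimulated genes 0.216 against 0.156 (permutation, adjusted p = 0.0005) and immediate-early genes 0.199 against 0.148 (permutation, adjusted p = 0.000714). Ribosomal protein genes (0.126 against 0.136) and nuclear-encoded oxidative phosphorylation genes (0.123 against 0.125) did not exceed their matched lists (permutation, adjusted p = 0.989 and 0.777). The TLR4 receptor and adaptors (0.132 against 0.132) and glycolysis and HIF-1 targets (0.143 against 0.139) were not wider than chance either (permutation, adjusted p = 0.575 and 0.363). In all, 13 of 25 lists were wider than chance in a permutation that treats members as independent although many are co-regulated. Among them were mitochondrially encoded mRNAs (0.410 against 0.144) and nuclear-retained RNAs (0.439 against 0.170). Redox and iron stress genes (0.184 against 0.150), antigen presentation genes (0.166 against 0.142) and macrophage markers (0.180 against 0.154) were among them too. Replicate 3 carried much of this in 3 lists: without it the coefficient was 0.182 for mitochondrially encoded mRNAs, 0.167 for chemokines and 0.140 for interferon-stimulated genes. Without replicate 2 the number was 7, and with the SD of log2(TPM + 1) as the measure it was 8; immediate-early genes (permutation, adjusted p = 0.106) and NF-kB feedback and subunits (permutation, adjusted p = 0.584) were no longer wider without replicate 2, nor interferon-stimulated genes without replicate 3 (permutation, adjusted p = 0.0945).

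Directions differed by list. All 27 interferon-stimulated genes were highest in replicate 3, with median deviations of -0.32, -0.09 and 0.42 log2 in replicates 1, 2 and 3, against 38.1% of all tested genes highest there. Lysosome and phagocytosis genes were highest there too for 20 of 24 (14 of 24 in TPM rescaled to protein-coding genes), and antigen presentation genes for 13 of 14, but for 5 of 14 in rescaled TPM. Ifnb1 varied 7.14-fold and Cxcl10 3.25-fold. Of 17 tested cytokines and enzymes, 0 were highest and 11 lowest in replicate 2 (median deviations 0.23, -0.49 and 0.16), as were 11 of 16 chemokines and 15 of 17 genes of NF-kB feedback and subunits, against 29.1% of all genes lowest there. Il6 varied 4.96-fold, Nos2 4.22-fold and Tnf 2.08-fold between replicates. Macrophage markers were lowest in replicate 1 for 11 of 15, and for 9 of 15 in rescaled TPM. In unscaled TPM, which depends on the share of short RNAs, 12 of 15 were lowest in replicate 2. Mitochondrially encoded mRNAs were lowest in replicate 3 for 12 of 13.

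**Figure D4:**
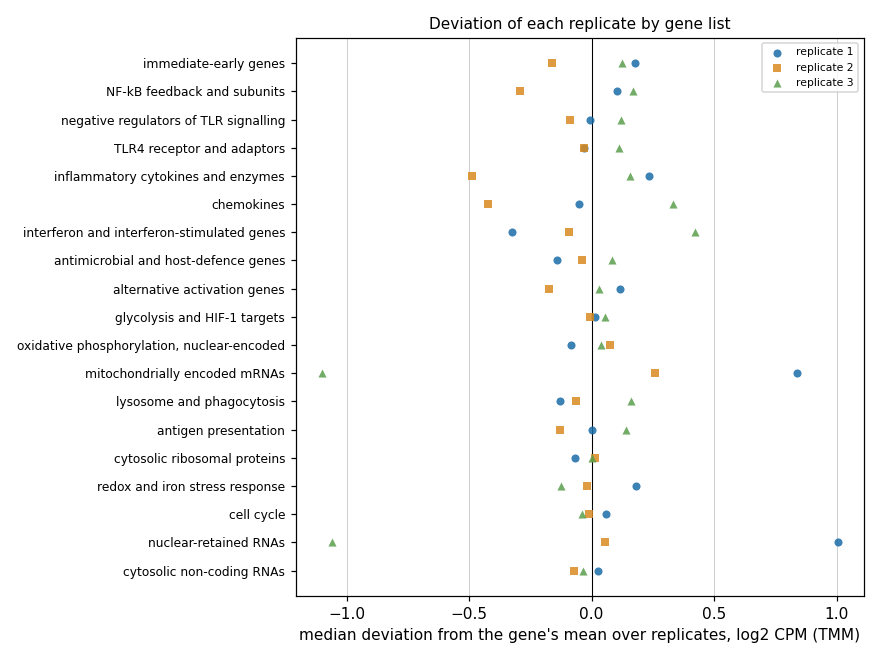
Median deviation of each gene list from its genes' means over replicates, in log2 CPM with TMM scaling, 1 point per replicate. Nuclear-retained RNAs and mitochondrially encoded mRNAs spread widely, from about 1.00 and 0.84 in replicate 1 to -1.06 and -1.10 in replicate 3.

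Over all genes, 9747 of 13827 with a mean count of at least 10 (70.5%) varied between replicates beyond counting error, and the common biological coefficient of variation was 0.226. The test sets cultures against counting error alone, so most abundant genes pass and passing says nothing of a direction: 27 of 27 interferon-stimulated genes and 16 of 17 genes of NF-kB feedback and subunits passed over all genes, and 27 and 17 adjusted over the list alone. Values correlated across genes at Pearson's r of 0.989 to 0.992 between pairs of replicates on the log2 scale; genes are not independent replicates. The 10 genes with the largest ratio of highest to lowest replicate were mostly non-coding or uncertain. Gm49369 (27.7-fold) overlaps Ctsd on chromosome 7 on the same strand. The snRNA genes Gm24497 and Gm24924, the snoRNA gene Rnu3a and mt-Co3 had posterior SDs of 39.1% or more of their counts. The others were Xist, Gm26917, its neighbour Gm42418 (6.71-fold), the X-linked Gm14636 (7.89-fold) and the snoRNA gene Gm22988 (6.31-fold). Gm42418 lies inside the rRNA-annotated gene CT010467.1 on the opposite strand. Without a stated strand setting, reads of the overlapping genes could not be told apart.

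Several response genes were read out as mixtures of annotated transcripts. Of 267 listed genes with a mean TPM of at least 10, 84 had 2 or more transcripts at 10% or more of the gene's TPM in every replicate. Irf7 divided into Irf7-201 at 48.5% ± 1.59, Irf7-203 at 25.3% ± 1.65 and Irf7-202 at 16.4% ± 0.562 (SD, n = 3). For the G-protein regulator Rgs1, the leading transcripts were annotated as subject to nonsense-mediated decay (58.8% ± 2.35) and as retaining an intron (35.2% ± 4.35). Il4ra had 54.1% ± 3.99 on a transcript annotated for nonsense-mediated decay, and Il1rn 74.6% ± 0.670 on Il1rn-201. Shares differed by table: Irf7-203 held 13.4% ± 0.692 and the Il4ra decay transcript 78.4% ± 2.10 in the second, and Csf1r-202 held 53.1% ± 12.6 in the first and 5.84% ± 0.141 in the second. The second table gave 69 genes, 56 of them among the 84. At a share of 20% the number was 45.

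The 2 transcript tables ranked RNAs of 1 library broadly alike but differed in scale and in the levels of some features. Across 141767 transcripts, log2(TPM + 1) correlated at Pearson's r of 0.924, 0.927 and 0.935 and Spearman's rho of 0.812, 0.819 and 0.835 in replicates 1, 2 and 3. Protein-coding genes held 33.3%, 26.1% and 37.0% of TPM in the first quantification and 19.6%, 9.70% and 10.9% in the second; after rescaling to coding genes their r was 0.991, 0.994 and 0.995. List medians in TPM were mostly lower in the second, for example 57.7 against 151 for interferon-stimulated genes and 20.97 against 48.1 for immediate-early genes. Exceptions near 0 were T and NK cell markers (0.011 against 0.00333) and sex-linked genes (0.0566 against 0.0). Of 22133 transcripts with a TPM of at least 1 in either table, 2059 differed over 2-fold the same way in all 3 replicates. Of these, 1765 were higher in the first table. TPM was not rescaled for this count, so the lower coding share of the second table enters the count and its direction. Without replicate 1 the number of differing transcripts was 8150, and with a pseudocount of 0.1 it was 5128.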

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

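Values outside the compared genes come first, then 1 pattern in the fraction itself. The tests of nuclear carry-over, of RNA classes and of scaling were chosen only after the result was seen; the matched-gene tests were fixed before their result was computed.

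PhiX, a bacteriophage genome that is commonly added to sequencing runs and is listed in the gene table but used in no comparison, had 37691, 28334 and 13416 expected counts in replicates 1, 2 and 3, above the 3 counts that a count of 0 allows. The tRNA entries had 4.98 expected counts in replicate 2. In the second quantification, 5 short features (the pseudogenes Gm12895 and Gm12896 and the microRNA entries Gm24270, Gm24245 and Gm23935) held 49.0%, 69.1% and 73.6% of TPM in replicates 1, 2 and 3 but 4.75%, 13.7% and 9.18% of its estimated counts, and were listed at 0 in the first.

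Nuclear-retained RNAs were higher in replicate 1 than in replicate 3 in 9 of 9 tested members, with a median log2 difference of 2.06, and mitochondrially encoded mRNAs in 12 of 13, with a median of 1.94. Protein-coding genes nearest in length, GC share and level differed by -0.18 for the nuclear-retained RNAs and -0.024 for the mitochondrial mRNAs. The nearest genes were taken however far they lay, so these values cannot decide on length or base composition. Scaling of the libraries is argued against, since the nuclear-retained list stood 2.21 log2 above level-matched random lists, outside their central range. Unequal carry-over of nuclei may have a part in the nuclear RNAs: 54 genes annotated as sense intronic, which the list does not hold, differed the same way by a median of 0.81, as did 6 small Cajal body RNA genes (1.48), 25 snoRNA genes (0.56, quartiles -0.36 and 0.88, 10 with posterior SDs of 10% or more) and 536 unclassified genes of the annotation class TEC (0.92). Among these classes the exception was 26 snRNA genes, at -0.15 (quartiles -0.32 and 0.33), of which 20 had such posterior SDs from shared reads. Within the nuclear-retained list, 7 members were highest in replicate 1 and 2 in replicate 2. Those 2 were Rn7sk (7841, 8918 and 4455 CPM in replicates 1, 2 and 3) and Rmrp (930, 1367 and 670). Carry-over thus stays a hypothesis, which the snoRNA and snRNA genes do not settle. The mitochondrial part is open too, and no biological explanation was tested because all 3 libraries belong to 1 group.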

How the results depend on the processing

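Alternatives chosen after seeing the data were TPM rescaled to protein-coding genes and the fit to nuclear protein-coding genes only. No paired analysis was possible because the labels give 1 group. No fixed difference changed sign under any alternative run, and of 122 alternative values of the main results 108 stayed within 1.5 times the count or 1 SD. Of 257 values of list levels and marker differences 121 moved, and of 145 list spread calls 16 were lost and 7 gained. Counts set by a limit followed it, by construction: 5802 expressed genes at a TPM of 5, 45 genes at an isoform share of 20%, and 980 and 352 differing transcripts at a TPM of 10 and over 4-fold. With a pseudocount of 0.1, differing transcripts numbered 5128, chemokines minus cytokines was 4.36 and Arg1 minus Nos2 -5.43, both by construction of low values. In the second quantification, NF-kB feedback and subunits minus cytokines was 1.78 and chemokines minus cytokines 3.58; the cause was not tested. With members of mean TPM of at least 1, NF-kB feedback and subunits minus cytokines was 1.495, since low cytokines drop out, and with TPM rescaled to protein-coding genes Arg1 minus Nos2 was -3.90, since the pseudocount then weighs less. The number of wider lists was 8 by SD of log2(TPM + 1); the cause was not tested. Leaving out 1 replicate gave 7 to 15 wider lists, the lowest without replicate 2, and 2203 to 8150 differing transcripts, the highest without replicate 1, the library in which the short features took least of the second quantification. The fit to nuclear protein-coding genes gave 8268 of 11656 genes varying and a coefficient of variation of 0.160. Arg1 had 0, 1 and 1 counts, so its differences from Nos2 follow the pseudocount and bound no fold.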

Other observations

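Genes named in the next paragraph were chosen after their values were seen, and the test of an early response and those of scaling after the result; the matched-gene tests were fixed before their result was computed.

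Some single genes that varied between replicates in CPM are given here, and they were not tested as a group. Of all tested genes, 70.5% varied beyond counting error. The kinase Plk2 stood at 633, 204 and 838 CPM in replicates 1, 2 and 3, and the growth factor Csf1 at 185, 59.0 and 238. Of members of the fixed lists, the stress cytokine Gdf15 stood at 346, 169 and 573, and Tnfsf9 at 280, 97.4 and 252. Highest in replicate 3 were Tgtp1 at 20.0, 40.3 and 111, Ifit1bl1 at 150, 156 and 594, and Ly6a at 70.1, 55.2 and 203, picked for that place. Mir155hg, the precursor gene of an inflammatory microRNA, stood at 41.7, 10.2 and 6.64, and the Cajal body RNA Scarna10 at 38.6, 15.3 and 7.07, both highest in replicate 1. The scavenger receptor Marco (284, 549 and 244) and Saa3 (1263, 3332 and 1805), of the antimicrobial list, went the other way from the cytokines, with replicate 2 highest.

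Interferon-stimulated genes were higher in replicate 3 than in the mean of replicates 1 and 2 for 27 of 27 genes, with a median log2 difference of 0.63. Genes matched on length, GC share and level differed by 0.17 and the list stood 0.45 above level-matched random lists, outside their central range of 0.07 to 0.30 around a median of 0.18. Scaling thus does not account for the whole of it, although level-matched genes shifted the same way. The genes nearest in length and GC share were taken however far they lay, so their value cannot decide on length or composition. All 27 stayed highest in replicate 3 with median-ratio factors and with TPM rescaled to protein-coding genes, and 26 in the second quantification. A stronger interferon response in that culture may be a source, as a hypothesis that no group of the design tests. Replicate 3 stood apart in other lists as well: lysosome and phagocytosis genes were highest there for 20 of 24, antigen presentation genes for 13 of 14 (5 of 14 in TPM rescaled to protein-coding genes), and nuclear-retained RNAs and mitochondrially encoded mRNAs lowest, with median deviations of -1.06 and -1.10. A difference of that library as a whole is thus open.

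Genes of the cytokine, chemokine and NF-kB lists were lower in replicate 2 than in the mean of the others for 41 of 50 genes, with a median log2 difference of -0.55. Matched genes differed by -0.008, but they were taken however far they lay, so this value cannot decide on length and composition. The lists stood -0.53 from level-matched random lists, which argues against scaling. A smaller early response in that culture may have a part: of 22 immediate-early genes, a list of its own, 14 were lowest in replicate 2, against a median of 7 and an upper limit of the central range of 11 in level-matched random lists. Those draws treat co-regulated genes as independent and describe 1 library, so they give no test of a difference between cultures. The list's median deviation was lowest in replicate 2 (0.18, -0.16 and 0.12), but its median level in replicate 3 (137, 121 and 108 CPM), where Fos (236, 161 and 96.4) and Nr4a1 (28.2, 13.9 and 4.98) were lowest. Timing, dose and cell state of the cultures stay open, as no library of another condition is among these.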
